A study of Mus musculus with 8 samples.

How the data were processed

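RNA was measured in 8 samples of mouse follicular B cells, the recirculating B cells of the spleen, 4 from mice with both alleles of the Kindlin-3 gene floxed and carrying mb1-Cre (Kindlin-3 KO) and 4 from floxed mice without Cre (control). Per the labels' protocols, splenocytes were frozen, thawed, stained on ice and sorted on CD19, B220 and medium levels of CD21 and IgM, and total RNA was taken up immediately after the sort. The RNA was amplified and biotin-labelled with a kit for small inputs and hybridised to an Affymetrix whole-transcript array, on which a row summarises the probes of a transcript cluster. The labels number the replicates 1 to 4 in each group and do not say that each sample came from a separate mouse, so the p-values measure the spread between these samples, which may be technical in part.

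The deposited values are log2 expression values that the authors summarised by robust multi-array average (RMA) with the R package oligo, per the submitters' processing notes. The versions, the array annotation and the genome build are not given in the sources used here, and the log2 scale is read from the range of the values. The values are not centred per gene, and their direction is that of a single-colour array. The median over all 72688 rows was 4.05, 3.68, 3.72 and 3.68 in control replicates 1 to 4 and 3.63, 3.64, 3.68 and 3.64 in Kindlin-3 KO replicates 1 to 4. The values hold no detection calls, so a level near 3 may be background, and the number of arrays limits the precision. Scanner files were not analysed here.

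Rows were named through the platform annotation, in which 30638 rows have 1 gene symbol, 2176 have several and 39874 rows are not listed. Rows with several symbols or none entered only the alternative that tests all rows. Symbols were checked through the Entrez identifier against a RefSeq gene table of assembly GRCm38.p6, which matched 22596 rows and changed 0 symbols. That table was used only for names and for which genes neighbour each other, and no coordinates are printed because the build of the array annotation is not given. Where a gene had more than 1 row (354 genes), the row with the highest mean over the 8 arrays stood for it, which left 30176 genes. Rows of closely related genes, such as immunoglobulin V segments and the receptor families of the nose, can share signal by cross-hybridisation and are uncertain as single genes.

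Kindlin-3 KO was compared with control in limma 3.58.1 under R 4.3.3, with lmFit and eBayes on the deposited values of all 8 samples, group as the only term, two-sided, and Benjamini-Hochberg adjustment over the 30176 genes with a threshold of 0.05. Log2 fold changes are Kindlin-3 KO minus control and are given with the standard error of the moderated fit. For Fermt3 and Cd79a an exact two-sided permutation test of the difference of means over all 70 labelings stands beside the fit, and 0.0286 is the smallest p it can give. Same-numbered samples of the groups were compared by the correlation of their deviations from the group means across genes, which was -0.48, 0.11, -0.23 and 0.26 for replicates 1 to 4. Control replicate 1 weighs on the control mean, and without it the correlation was 0.25, 0.40 and 0.38 for replicates 2 to 4. Over all 8 arrays no control correlated best with the Kindlin-3 KO sample of its own number, and in Kindlin-3 KO only replicate 4 did so. Without control replicate 1, correlations between different numbers are not given here. A pairing by number is therefore not shown, and it is allowed for only where control replicate 1 is left out, from the data and not from the labels. Gene lists were tested with limma's camera at a preset correlation of 0.01 between genes, Benjamini-Hochberg adjusted over the 34 lists with at least 5 measured members. Camera with a correlation estimated from the data and the rotation test fry were run beside it. A list's shift is the mean log2 fold change of its members minus that of all other genes. The tests, the gene lists and the rule for named genes were fixed before the data were examined. That rule takes Fermt3 and Cd79a, the 12 genes of largest increase and the 12 of largest decrease past the adjusted threshold, filled up where too few pass with the genes of smallest unadjusted p in that direction. It leaves out predicted and small RNA names and the V, D and J segments, and for each list it takes up to 4 members of smallest unadjusted p.

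The steps were tested on simulated log2 values with the means and spreads of the 30176 genes, 4 samples against 4, in which 200 genes were changed. Those means and spreads were taken without control replicate 1, which the main fit kept. The recovery with no array narrowed is therefore not that of the main fit. Of 67 genes changed by 0.5 log2 units, 58.2% were recovered, of 67 changed by 1 unit 91% and of 66 changed by 2 units 100%, with 8 false calls. When the range of 1 control array was narrowed by a factor of 0.7, recovery was 4.48%, 73.1% and 98.5%, with 3 false calls. In simulated values with no group effect camera called 0 of 34 lists, and 14 lists after that control array was narrowed, of which cyclic loess left 0. Correlation between genes was not among the simulated settings, so these counts do not carry over to the real arrays. There, splits of the samples into 2 groups gave 1 to 12 lists after cyclic loess and 0 to 20 without control replicate 1. A shift of 0.5 given to the complex I list was called.

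Alternatives were eBayes with trend and robust priors, array weights, quantile normalization, centring on the median, cyclic loess, a filter on dim genes, all rows of the table, the mean of a gene's rows, a minimum log2 fold change of 1, the replicate number as a block, and leaving out each sample in turn. Chosen after seeing the data were cyclic loess over the 7 arrays other than control replicate 1, array weights after cyclic loess, scale normalization, the 6 samples with low Xist, Xist level as a block, and the replicate block without control replicate 1.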

Results

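Gene expression was measured on whole-transcript arrays in follicular B cells sorted from the spleens of mice with Kindlin-3 deleted under mb1-Cre (n = 4) and of floxed mice without Cre (n = 4). Kindlin-3, encoded by Fermt3, binds the tails of integrin beta chains and is needed for integrin activation in blood cells, and Cre is driven from mb1, which is Cd79a, a chain of the B cell receptor complex. The comparison asks which transcripts of follicular B cells differ when Kindlin-3 is lost from the B lineage. Only the Kindlin-3 KO mice carried Cre, so effects of Cre or of the altered Cd79a allele cannot be told from those of Kindlin-3 loss. Of the 8 arrays, control replicate 1 stood apart. The SD of its values over all rows was 1.45, against 1.78 to 1.83 in the other controls and 1.83 to 1.92 in Kindlin-3 KO, and it correlated with the other arrays at r = 0.901 to 0.937, against 0.984 to 0.998 among the other 7. These correlations are across genes, which are not independent replicates. Its genes of high level read lower and its genes of low level read higher than in the other controls, so values without it are given for the lists that passed and for genes of the lists that it moved by over 1.5 times.

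Fermt3 read 6.61 ± 0.51 log2 units in control (SD, n = 4) and 6.11 ± 0.15 in Kindlin-3 KO (SD, n = 4), a log2 fold change of -0.51 (SE 0.23). The difference did not pass the limma test (adjusted p = 0.409) or the exact permutation test (p = 0.143). Control replicate 1 read 5.93, just below the Kindlin-3 KO range of 5.97 to 6.31. Control replicates 2 to 4 read 7.08, 6.54 and 6.91, all above that range. Without control replicate 1 the log2 fold change was -0.74 (SE 0.14, adjusted p = 0.0897), with an exact permutation p of 0.0286, the smallest that test can give. That p takes all 35 labelings. Only 8 of them part all 3 pairs of equal replicate number, too few for a share under 0.05. The gene has 1 row on the array, and whether its probes lie in the deleted part of the gene is not known here, so a remaining signal in Kindlin-3 KO measures no remaining protein. Cd79a, whose allele carries the Cre, read 8.93 ± 1.21 in control and 9.32 ± 0.14 in Kindlin-3 KO (SD, n = 4 each), a log2 fold change of 0.39 (SE 0.51, adjusted p = 0.587, exact permutation p = 0.8286). Its direction turned without control replicate 1 (-0.20) and after cyclic loess (-0.26).

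**Figure D1:**
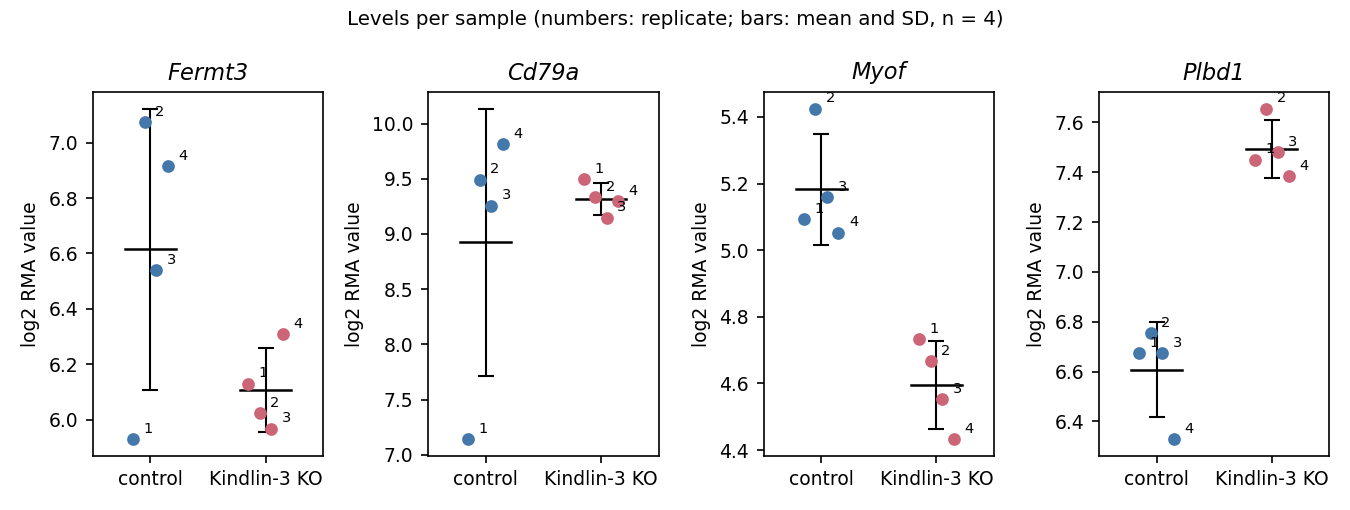
Log2 RMA values of Fermt3, Cd79a, Myof and Plbd1 in each sample, with replicate numbers beside the points and bars for the mean and SD (n = 4 per group). Control replicate 1 is the lowest control for Fermt3 (5.93) and Cd79a (7.14), while Myof and Plbd1 do not overlap between the groups.

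No gene passed the adjusted threshold in limma. The smallest adjusted p was 0.409, and 3138 of 30176 genes had an unadjusted p under 0.05, 2145 of them higher and 993 lower in Kindlin-3 KO, where 1509 would be expected by chance. That count was 4720 without control replicate 1, 4411 without control replicate 2 and 4726 without control replicate 4. It was 1287, 1494 and 1925 without Kindlin-3 KO replicates 1, 2 and 4. The excess of higher genes was smaller after cyclic loess, with 1620 higher and 1139 lower. Over all rows of the array it was absent, with 2903 higher and 2979 lower. All rows together have a lower median level than the tested genes (3.68 against 4.08 in control replicate 2). Low levels read lower in Kindlin-3 KO, so that balance does not bear on the excess among the tested genes. The groups did not overlap for 4475 genes (14.83%) as deposited and for 2414 (8%) after cyclic loess, where chance gives 2.857%. That chance share is an average and gives no spread for genes that shift together on an array. The genes of smallest unadjusted p are therefore given as values, none of them past the test and each with an adjusted p of 0.409. Among those higher in Kindlin-3 KO, Plbd1, a lysosomal phospholipase-like protein, read 6.61 ± 0.19 in control and 7.49 ± 0.12 in Kindlin-3 KO (log2 fold change 0.88, SE 0.12). Tagln2, an actin-binding protein, read 7.42 ± 0.41 and 8.51 ± 0.22 (1.09, SE 0.21). Pglyrp1, a peptidoglycan-binding protein, differed by 1.07 (SE 0.20) and Tbca, a tubulin-folding cofactor, by 1.06 (SE 0.18). Dusp4, a phosphatase of MAP kinases, differed by 0.89 (SE 0.16), Pltp, a phospholipid transfer protein, by 0.86 (SE 0.15), and Cd44, the hyaluronan receptor, by 0.58 (SE 0.11). The others were Snrnp25 (0.83), Anxa5 (0.74), Blvrb (0.57), Cnpy2 (0.53) and Cyb561d2 (0.51). All 12 had the same direction after cyclic loess, with smaller differences, such as 0.45 for Plbd1 and 0.20 for Blvrb.

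Among the genes lower in Kindlin-3 KO, Myof, a ferlin family membrane protein, read 5.18 ± 0.17 in control and 4.60 ± 0.13 in Kindlin-3 KO (SD, n = 4 each; log2 fold change -0.59, SE 0.11). Apoe, the lipid carrier apolipoprotein E, read 7.40 ± 0.12 in control and differed by -0.40 (SE 0.09). Csrp2, a LIM domain protein, read 6.28 ± 0.06 and 5.95 ± 0.07 (-0.33, SE 0.08). Tigd3 differed by -0.37 (SE 0.09) at a control level of 4.24. The other 8 were Vmn2r-ps12, Vmn1r168, Olfr672, Olfr594, Olfr58, Olfr875, Gstt4 and Adam30, with control levels of 2.98 to 4.21 and differences of -0.50 to -0.33. None of the 12 passed the test (adjusted p = 0.409). After cyclic loess all 12 were lower too, Apoe and Csrp2 by more (-0.86 and -0.56) and the other 10 by less, such as -0.15 for Olfr875 and Adam30. Of the 24 named genes, Vmn1r168, Blvrb, Apoe and Pglyrp1 lie within 163 genes of Cd79a on chromosome 7.

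Without control replicate 1 the fit called 1 gene, which falls outside the rule for named genes and is named after its values were seen. Myadm, a membrane protein of myeloid differentiation, read 7.33, 7.52 and 7.15 in control replicates 2 to 4 and 8.49 to 8.69 in Kindlin-3 KO, a log2 fold change of 1.25 (SE 0.09, limma adjusted p = 0.0375). With the replicate number as a block over the 3 pairs left, it did not pass (adjusted p = 0.1495). Its log2 fold change over all 8 samples was 1.61 (SE 0.32, adjusted p = 0.409) and after cyclic loess 1.08 (adjusted p = 0.482). With array weights limma called 1047 genes, 891 higher and 156 lower in Kindlin-3 KO. Among them were Fermt3 at -0.75 (adjusted p = 0.026) and Myadm (adjusted p = 0.00404). The weights, estimated from these same arrays, were 0.044 for control replicate 1 and 6.19 for Kindlin-3 KO replicate 2. In the other arrays they were 0.71 to 1.75, so the 1047 calls lean on Kindlin-3 KO replicate 2. Array weights after cyclic loess called 0 genes in limma, with 4286 at an unadjusted p under 0.05.

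The fold change depended on expression level. In the decile of genes with the lowest mean level the median log2 fold change was -0.19, and in the decile with the highest it was 0.59. Without control replicate 1 these were -0.08 and 0.24, and after cyclic loess they were 0.00 and 0.00. The median over all genes was -0.09 as deposited and 0.02 after each array was centred on its median. Each list is therefore given as its shift against all other genes, with the shift or the adjusted p after cyclic loess for the lists that passed.

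**Figure D2:**
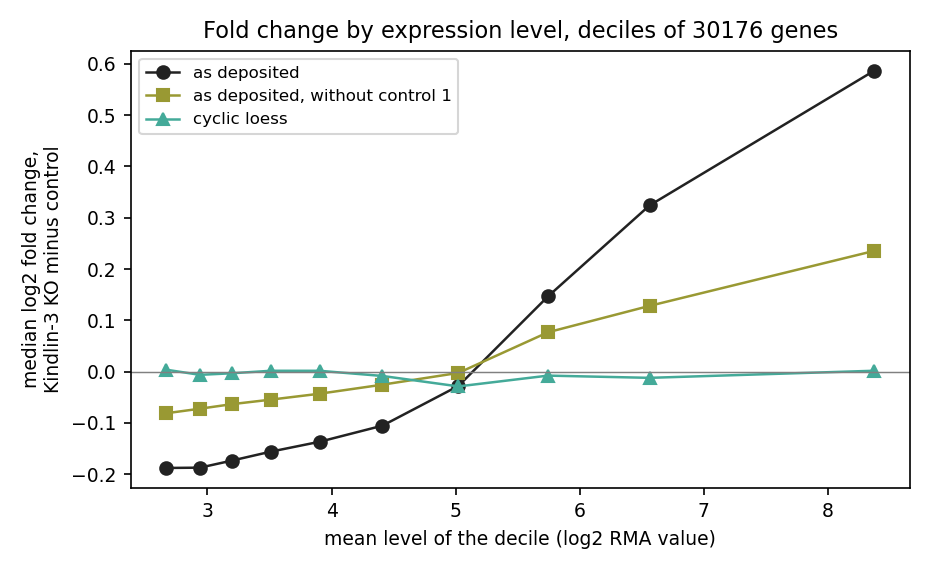
Median log2 fold change (Kindlin-3 KO minus control) of deciles of the 30176 genes against their mean level in log2 RMA units, as deposited, without control replicate 1 and after cyclic loess. The deposited values climb from -0.19 to 0.59, the values without control replicate 1 from -0.08 to 0.24, and the values after cyclic loess stay near 0.

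Of the 34 lists, 21 passed camera with the preset correlation, 18 higher and 3 lower in Kindlin-3 KO. With an estimated correlation 0 lists passed (smallest adjusted p = 0.418), and fry called 0 lists (smallest adjusted p = 0.301). Without control replicate 1, 18 lists passed, and after cyclic loess 4 passed, namely the kappa V segments, the heavy V segments, respiratory complex I and the markers of monocytes and macrophages. With an estimated correlation 0 lists passed after cyclic loess (adjusted p = 0.636 for complex I and 0.785 for the other 3), and 0 without control replicate 1. Each of the 35 ways to split the 8 samples 4 against 4 has control replicate 1 in 1 of its groups, and all gave 16 to 26 lists. After cyclic loess 25 of the 35 gave at least as many as the 4 of the real groups. No member of any list passed the adjusted threshold over all genes.

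The V segments of the immunoglobulin kappa chain stood higher in Kindlin-3 KO, with a list mean of 5.76 ± 0.71 in control and 6.45 ± 0.04 in Kindlin-3 KO (SD, n = 4 each). Of 86 measured segments 76 read higher, and 8 passed when adjusted over the list alone and 0 over all genes. Without control replicate 1, 37 passed when adjusted over the list alone. Igkv3-2 read 6.64 ± 0.26 and 7.42 ± 0.19 (log2 fold change 0.79, SE 0.15), and Igkv6-29 differed by 0.70 (SE 0.14). Igkv13-85 differed by 0.86 (SE 0.18) and Igkv13-84 by 0.95 (SE 0.22). The list's shift was 0.69 (camera adjusted p = 7.27e-17; adjusted p = 0.418 with an estimated correlation). It was 0.32 without control replicate 1 (adjusted p = 3.38e-17) and 0.47 after cyclic loess (adjusted p = 7.16e-13; adjusted p = 0.785 with an estimated correlation), or 0.23 over the 7 arrays other than control replicate 1 (adjusted p = 5.38e-11). The list means of the 2 groups did not overlap in any of these (exact permutation p = 0.0286, the smallest possible). Over 7 arrays that p takes all 35 labelings. Only 8 of them part all 3 pairs of equal replicate number, too few for a share under 0.05. Segments that share sequence are uncertain singly.

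The V segments of the heavy chain showed a shift of 0.50 (113 measured, 100 higher, 1 past the threshold adjusted over the list alone; camera adjusted p = 7.6e-17; adjusted p = 0.418 with an estimated correlation). The shift was 0.23 without control replicate 1 (adjusted p = 2.95e-13), where 9 segments passed when adjusted over the list alone. After cyclic loess the shift was 0.25 (adjusted p = 2.53e-06; adjusted p = 0.785 with an estimated correlation), and over the 7 arrays other than control replicate 1 it was 0.13 (adjusted p = 8.50e-05). Ighv8-2 read 5.21 ± 0.22 in control and 6.09 ± 0.19 in Kindlin-3 KO (log2 fold change 0.89, SE 0.14), and Ighv1-7 differed by 0.82 (SE 0.22). Ighv10-1 differed by 0.43 as deposited and by -0.22 after cyclic loess, and Ighv6-7 by -0.35 (SE 0.10). The list means of the groups overlapped, since control replicate 4 read 6.54 and the lowest Kindlin-3 KO sample 6.49 (exact permutation p = 0.0857). Of the constant regions, measured by 4 members and so not tested as a list, Ighm read 11.52 ± 1.04 and 12.15 ± 0.17, a log2 fold change of 0.63 (SE 0.45) that was 0.13 without control replicate 1 and turned to -0.22 after cyclic loess. Ighg2b (0.37, adjusted p = 0.518, and 0.23 without control replicate 1), Ighe (-0.20, adjusted p = 0.409, and -0.11) and Ighg1 (adjusted p = 0.994) did not pass either. No lambda V segment was measured by a row with 1 symbol.

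**Figure D3:**
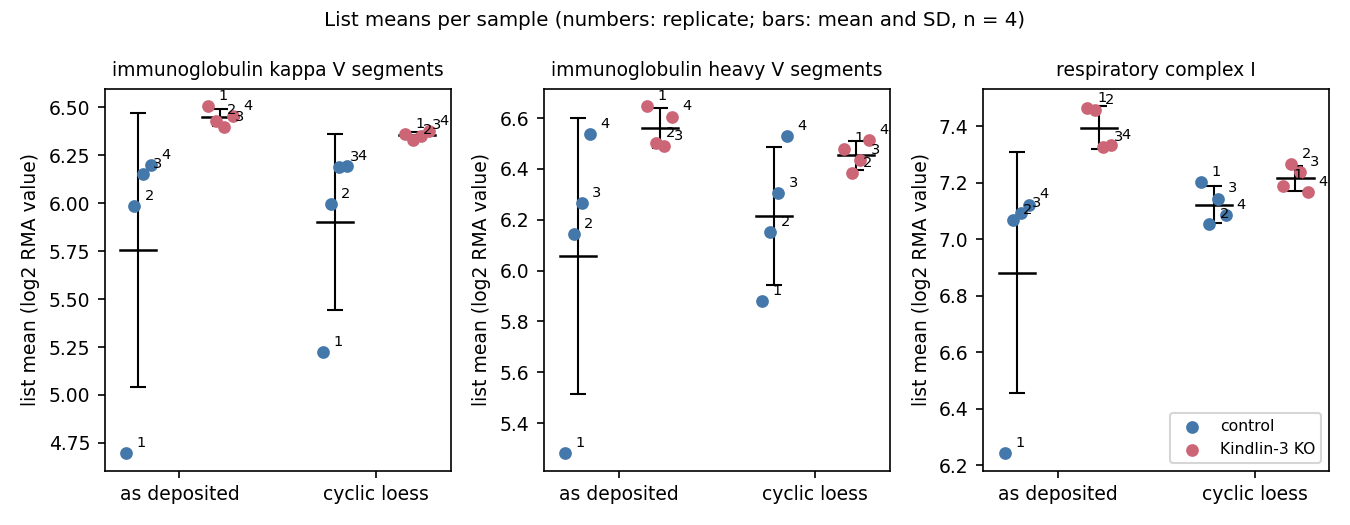
Mean log2 RMA value of the kappa V segments, the heavy V segments and respiratory complex I in each sample, as deposited and after cyclic loess, with replicate numbers and bars for the mean and SD (n = 4 per group). The kappa V means do not overlap on either scale, the heavy V means overlap on both, and those of complex I overlap after cyclic loess only.

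Subunits of respiratory complex I, which passes electrons from NADH into the respiratory chain, read higher in Kindlin-3 KO for 32 of 32 genes, with 1 past the threshold adjusted over the list alone and a shift of 0.51 (camera adjusted p = 1.68e-15; adjusted p = 0.418 with an estimated correlation). Ndufa8 read 6.96 ± 0.06 and 7.40 ± 0.10 (log2 fold change 0.44, SE 0.09), Ndufb6 differed by 0.78 (SE 0.21), Ndufv1 by 0.45 (SE 0.12) and Ndufa9 by 1.09 (SE 0.34), or 0.71 without control replicate 1. The complex I shift was 0.29 without control replicate 1 (adjusted p = 3.38e-17), where 18 of 32 genes passed when adjusted over the list alone. After cyclic loess the shift was 0.11 (adjusted p = 0.0144; adjusted p = 0.636 with an estimated correlation), with 22 of 32 genes higher and Ndufa8 at -0.01. The list means then overlapped between the groups (exact permutation p = 0.0857). Over the 7 arrays other than control replicate 1 it was 0.13 after cyclic loess (adjusted p = 8.92e-06). Cytosolic ribosomal proteins had a shift of 0.51 (adjusted p = 6.91e-14; adjusted p = 0.418 with an estimated correlation; 40 of 43 higher, 0 past the threshold adjusted over the list alone), which turned to -0.03 after cyclic loess. Their shift was 0.25 without control replicate 1 (adjusted p = 3.88e-16), where 23 of 43 genes passed when adjusted over the list alone. Rpl27 differed by 0.94 (SE 0.34, and 0.56 without control replicate 1) and Rpl31 by 0.49 (SE 0.11). Ribosome biogenesis and MYC targets had 17 of 17 genes higher and a shift of 0.46 (adjusted p = 1.76e-06; adjusted p = 0.418 with an estimated correlation). Dkc1 differed by 0.70 and Odc1 by 0.82, and the shift was 0.22 without control replicate 1 (2 genes past when adjusted over the list alone) and 0.06 after cyclic loess (adjusted p = 0.52).

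Genes that B cells switch on after stimulation read higher in part. In the B cell activation list 14 of 20 genes were higher and 1, Cd44, passed when adjusted over the list alone, with a shift of 0.37 (camera adjusted p = 0.000302; adjusted p = 0.418 with an estimated correlation). Cd83, a surface marker of activated B cells, read 6.11 ± 1.07 in control and 7.40 ± 0.16 in Kindlin-3 KO (log2 fold change 1.29, SE 0.45). Ccnd2, a cyclin of the early cell cycle, differed by 0.90 (SE 0.30) and Slc7a5, an amino acid transporter, by 0.39 (SE 0.14). Leaving out control replicate 1 gave 0.79 for Cd83 and 0.56 for Ccnd2. Immediate early genes had a shift of 0.34 (15 of 20 higher, 2 past the threshold adjusted over the list alone, adjusted p = 0.000752). Those 2 were Egr1 at 0.41 (SE 0.09) and Klf6 at 1.34 (SE 0.31), beside Jun at 0.76 (SE 0.27) and Fos at 0.83 (SE 0.41). Fos read 5.92 ± 0.21 in control and 6.75 ± 0.96 in Kindlin-3 KO (SD, n = 4 each). The immediate early list mean was highest in Kindlin-3 KO replicates 1 and 2 (both 6.13). The groups overlapped, since Kindlin-3 KO replicate 4 read 5.74 and control replicate 3 read 5.83. CD40 and NF-kB targets had a shift of 0.39 (16 of 19 higher, adjusted p = 2.42e-05), with Cd40 at 0.68, Traf1 at 0.81, Bcl2a1d at 0.67 and Tnfaip3 at 0.36 (Cd40 and Bcl2a1d both at 0.44 without control replicate 1). With an estimated correlation the adjusted p was 0.418 for all 3 lists. Their shifts without control replicate 1 were 0.19, 0.22 and 0.16, all past camera, and 4, 2 and 1 genes passed when adjusted over the list alone. After cyclic loess the shifts were 0.17, 0.16 and 0.12 and none passed (adjusted p = 0.0561, 0.52 and 0.289). After cyclic loess over the 7 arrays other than control replicate 1 they were 0.11, 0.14 and 0.05, and none passed either (adjusted p = 0.0787, 0.429 and 0.608).

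Of the genes tied to integrins, 19 of 30 read higher, with a shift of 0.23 (adjusted p = 0.00779; adjusted p = 0.418 with an estimated correlation) that did not pass without control replicate 1 (0.07, adjusted p = 0.0614) or after cyclic loess (0.01, adjusted p = 0.921, and -0.01 over the other 7 arrays). Itgb2, the beta chain of LFA-1, read 6.79 ± 0.54 in control and 7.49 ± 0.24 in Kindlin-3 KO (log2 fold change 0.70, SE 0.26), and Rap1b, a GTPase that activates integrins, differed by 0.90 (SE 0.34). Itgb7 differed by 0.38 as deposited and by -0.13 after cyclic loess, and Icam1 by 0.44 (SE 0.20). For Itgb2, Rap1b, Itgb7 and Icam1 the values without control replicate 1 were 0.43, 0.50, 0.21 and 0.23. Homing receptors had a shift of 0.44 (14 of 18 higher, Cd44 past the threshold adjusted over the list alone, adjusted p = 0.000677; adjusted p = 0.418 with an estimated correlation). Cxcr5, which guides B cells into follicles, differed by 1.17 (SE 0.45), Gpr18 by 1.10 (SE 0.44) and S1pr4 by 0.60 (SE 0.22), which became 0.64, 0.60 and 0.36 without control replicate 1. The homing shift was then 0.14 (adjusted p = 0.0047, 5 genes past when adjusted over the list alone). After cyclic loess it was 0.17 over all 8 arrays (adjusted p = 0.289) and 0.02 over the 7 arrays other than control replicate 1 (adjusted p = 0.446).

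Lists of B cell identity and function were of high expression level. B cell receptor signalling (25 of 25 higher, shift 0.62, adjusted p = 1.40e-07), MHC class II presentation (13 of 13, 0.80, adjusted p = 1.37e-06), follicular B cells (9 of 9, 0.73, adjusted p = 0.000772) and the actin cytoskeleton (24 of 24, 0.63, adjusted p = 3.73e-11) all passed camera with the preset correlation. With an estimated correlation the adjusted p was 0.442, 0.431, 0.444 and 0.418, and after cyclic loess the shifts were 0.08, 0.12, 0.17 and 0.05, none past the test. The shifts of these 4 lists without control replicate 1 were 0.18, 0.33, 0.20 and 0.28, all past camera, and 1, 6, 1 and 15 genes passed when adjusted over the list alone. Examples were Grb2 (0.80, SE 0.31) and Cd79b (0.86, SE 0.42) of receptor signalling and Ctss (0.97, SE 0.31) and Ifi30 (1.02, SE 0.37) of antigen presentation. Fcer2a, the gene of CD23, differed by 0.96 (SE 0.45) and Diaph1 of the cytoskeleton by 0.69 (SE 0.26), while Ezr differed by 0.53 (SE 0.18) and by -0.07 after cyclic loess. Leaving out control replicate 1 gave 0.46 for Grb2, 0.39 for Cd79b, 0.63 for Ctss, 0.59 for Ifi30, 0.47 for Fcer2a, 0.42 for Diaph1 and 0.34 for Ezr. The unfolded protein response (14 of 14 higher, shift 0.48, adjusted p = 1.41e-05, Calr at 0.79) and survival and BAFF (10 of 14, 0.26, adjusted p = 0.00355, Mcl1 at 0.64) also passed. Their shifts were 0.18 and 0.12 without control replicate 1 (adjusted p = 3.27e-05 and 0.0118), and 3 and 2 genes passed when adjusted over the list alone, with Calr at 0.36 and Mcl1 at 0.39. Plasma cells passed too (10 of 16, 0.32, adjusted p = 0.0181, Slamf7 at 0.91 and Pou2af1 at 1.17), as did heat shock (8 of 12, 0.25, adjusted p = 0.0342, Hspe1 at 0.89), but neither of these passed without control replicate 1 (shifts of 0.11 and 0.07, adjusted p = 0.0614 and 0.151, with Pou2af1 at 0.55 and Hspe1 at 0.55). Heat shock passed with the replicate block over the 3 pairs left (adjusted p = 0.00832) and not without Kindlin-3 KO replicate 2 (adjusted p = 0.162). With an estimated correlation the adjusted p of the unfolded protein response, survival, plasma cell and heat shock lists was 0.418 to 0.442, and after cyclic loess 0.533 to 0.921, where heat shock turned to -0.01.

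Markers of other B cell subsets did not pass. Marginal zone B cells had a shift of 0.11 with a median log2 fold change of -0.08 and a test statistic pointing down (adjusted p = 0.963). Its member Myof (-0.59) passed when adjusted over the list alone, and Cd1d1 differed by -0.20 (SE 0.08) and Plac8 by 0.69 (SE 0.26). Germinal centre B cells (0.11, adjusted p = 0.732; Nuggc at -0.50, Bcl6 at 0.71), transitional and precursor B cells (median -0.11, adjusted p = 0.776; Vpreb1 at -0.36), B-1 cells (-0.07, adjusted p = 0.738; Plscr1 at -0.22) and age-associated and memory B cells (0.01, adjusted p = 0.576; Cxcr3 at 0.17) did not pass. The cell cycle (0.04, adjusted p = 0.738; Mcm3 at 0.67) and the type I interferon response (0.03, adjusted p = 0.576; Xaf1 at 0.48, Rsad2 at -0.35) did not pass either, and their medians of -0.07 and -0.01 had the opposite sign of mean and test. The shifts of marginal zone (-0.06) and germinal centre B cells (-0.01) and of the interferon response (-0.03) had the other sign without control replicate 1, and none passed. Plac8 was then at 0.41, Bcl6 at 0.43, Vpreb1 at -0.16 and Plscr1 at -0.05.

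Some markers of cells other than B cells read lower in Kindlin-3 KO. The list of monocytes and macrophages had 16 of 18 genes lower, none past the threshold adjusted over the list alone, with a shift of -0.32 (camera adjusted p = 0.00799; adjusted p = 0.547 with an estimated correlation). Its list mean was highest in control replicates 1 and 3 (4.74 and 4.51). The groups overlapped, since control replicate 2 read 4.12 and Kindlin-3 KO replicate 3 read 4.18. They overlapped after cyclic loess too (4.17 and 4.20 in the same samples). Lyz2, lysozyme of myeloid cells, read 5.95 ± 1.15 in control and 4.57 ± 0.50 in Kindlin-3 KO (log2 fold change -1.38, SE 0.53). Cd68 differed by -0.55 (SE 0.26) and Cd14 by -0.49 (SE 0.19, and -0.28 without control replicate 1). The list's shift was -0.22 without control replicate 1 (adjusted p = 0.0114, 1 gene past when adjusted over the list alone). After cyclic loess the shift was -0.23 (adjusted p = 0.0254; adjusted p = 0.785 with an estimated correlation), and over the 7 arrays other than control replicate 1 it was -0.18 (adjusted p = 0.0787). NK cell markers were lower in 11 of 11 genes (shift -0.32, adjusted p = 0.016; adjusted p = 0.547 with an estimated correlation; Gzma at -0.78, SE 0.35), and did not pass without control replicate 3 (-0.18, adjusted p = 0.204). Neutrophil markers were lower in 12 of 12 (-0.22, adjusted p = 0.0145; adjusted p = 0.547 with an estimated correlation; Ltf at -0.23, SE 0.10). The NK cell and neutrophil shifts without control replicate 1 were -0.26 and -0.10, both past camera, with Ltf at -0.15. Neither list passed after cyclic loess (adjusted p = 0.117 and 0.246). Dendritic cells (-0.20, adjusted p = 0.0745, with 0.0374 without control replicate 4 and a shift of -0.03, adjusted p = 0.646, without control replicate 1), erythroid cells (-0.18, adjusted p = 0.0698), endothelium and stroma (-0.11, adjusted p = 0.125), T cells (-0.03, adjusted p = 0.963) and platelets and megakaryocytes (-0.05, adjusted p = 0.738) did not pass. Without control replicate 1 the erythroid shift was -0.09, that of endothelium and stroma -0.07, of T cells -0.01 and of platelets and megakaryocytes -0.02, none past camera. The sex-linked list did not pass (0.15, adjusted p = 0.273, and -0.02 without control replicate 1). Xist read 9.46 in control replicate 4 and 9.54 in Kindlin-3 KO replicate 4 and 3.09 to 3.82 in the other 6 samples.

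**Figure D4:**
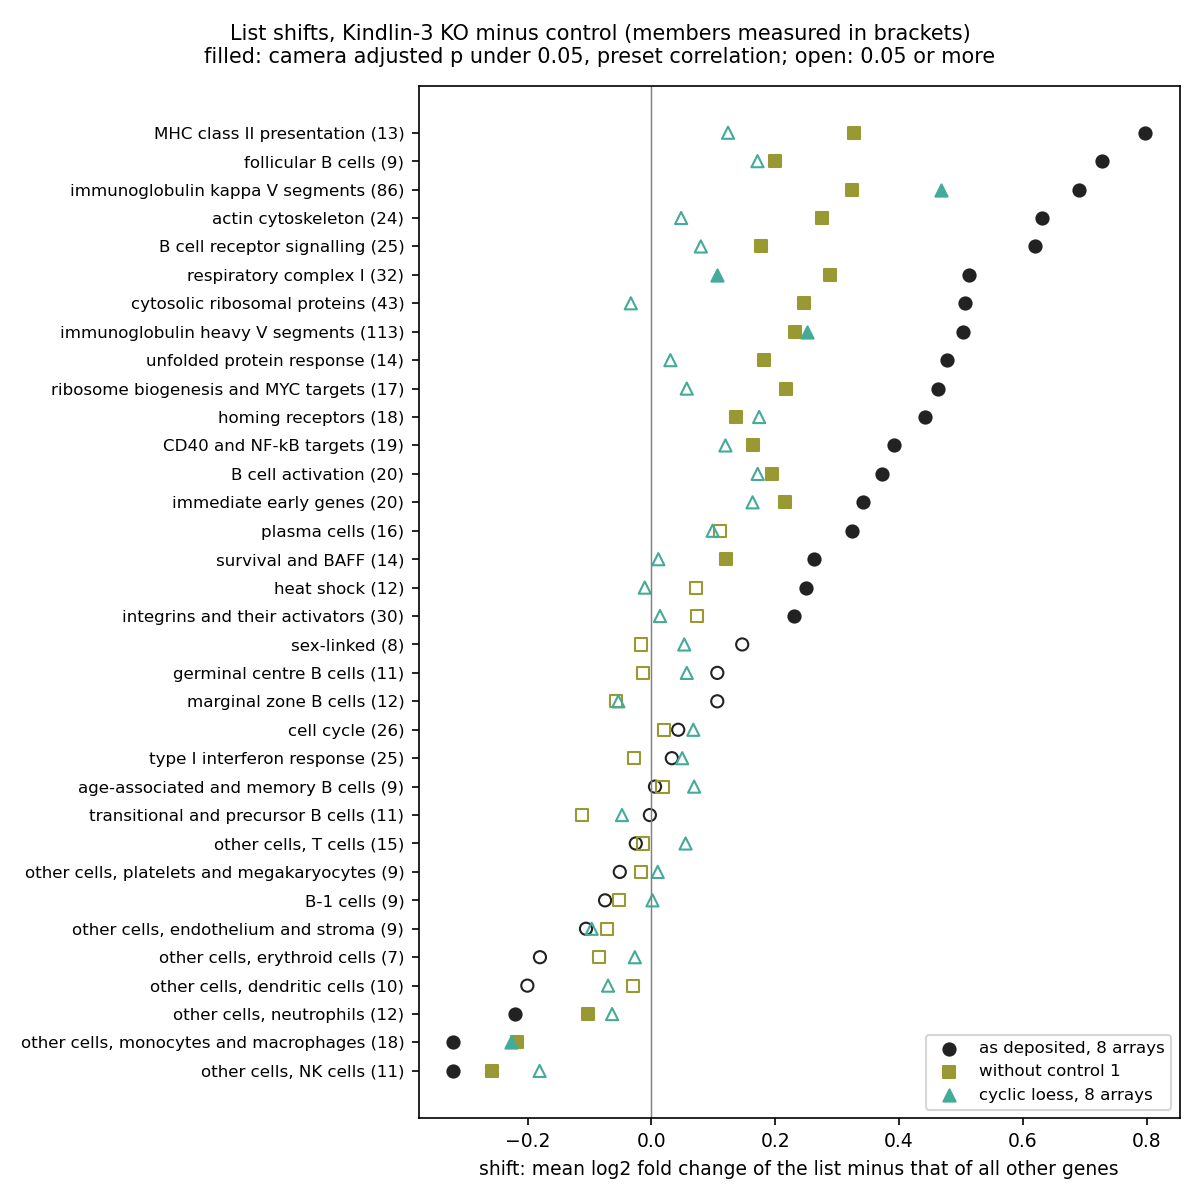
Shift of each of the 34 lists (mean log2 fold change of its members minus that of all other genes, Kindlin-3 KO minus control) as deposited, without control replicate 1 and after cyclic loess, with filled symbols for a camera adjusted p under 0.05 at the preset correlation. As deposited 21 lists are filled, without control replicate 1 18, and after cyclic loess 4.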

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

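The tests below on the level trend after cyclic loess, on control replicate 1 and on antibody-secreting cells were chosen after the results were seen, while the splits of the samples and the level-matched random lists were written down beforehand. A sample far from the other 3 of its group, by the gap to the nearest other over the group's range above Dixon's 95% critical value, was found in 19 of 122 groups examined, where chance gives about 6.1, and 17 of the 19 were control replicate 1. In 1 case an array feature outside the tested genes differed between the groups.

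That feature, TC0X00001690.mm.1, has no gene name in the annotation used here. It read 2.95 to 3.48 in the 4 controls and 6.09 to 6.76 in the 4 Kindlin-3 KO samples, a log2 fold change of 3.11 (SE 0.17). In 3 of the 4 controls it lay below the mean of the background control features of the array (3.64 to 4.20 in control replicates 1 to 3, 3.17 in control replicate 4), so the difference is a lower bound. Whether its probes match sequence introduced with the Cre allele was not tested, so it is not shown to be a change of a mouse gene. In limma over all 72688 transcript clusters it was the only one past the threshold (adjusted p = 0.00497; exact permutation p = 0.0286, the smallest that 70 labelings can give). It separated the samples by their labels with no overlap, control replicate 1 included.

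Control replicate 1 had the narrowest spread of values, 1.45 against 1.78 to 1.83 in the other controls (gap ratio 0.888). Among the named genes it was the lowest control for Tbca (6.99, ratio 0.837) and Dusp4 (4.58, ratio 0.899) and the highest for Tigd3 (4.40, ratio 0.842), Vmn2r-ps12 (4.51, ratio 0.921) and Vmn1r168 (3.77, ratio 0.893). Its list means were the lowest for integrins and their activators (5.55, ratio 0.901), homing receptors (5.28, ratio 0.882), B cell activation (5.27, ratio 0.832), plasma cells (5.27, ratio 0.909), the unfolded protein response (6.35, ratio 0.912), the actin cytoskeleton (7.30, ratio 0.855), kappa V segments (4.70, ratio 0.859), cytosolic ribosomal proteins (7.63, ratio 0.913) and respiratory complex I (6.24, ratio 0.939). They were the highest for neutrophils (4.23, ratio 0.956) and for platelets and megakaryocytes (4.56, ratio 0.928). Over all genes its deviation from the other controls had a slope of -0.297 on their level, against -0.032 to 0.034 for each of the other 7 arrays. The cytosolic ribosomal proteins, which every cell type holds, lay at -0.994 against the other controls. A narrow signal range lowers genes of high level with or without RNA of other cells, so this does not decide on that RNA beside a narrow range. After cyclic loess over all 8 arrays the ribosomal proteins lay above the other controls (8.88 against 8.51 to 8.68). Dendritic cell markers lay above the other controls as well on that scale (4.27 against 3.81 to 3.94). So did markers of neutrophils (3.88 against 3.73 to 3.77) and of endothelium and stroma (4.83 against 4.64 to 4.75). Markers of erythroid cells, of platelets and megakaryocytes and of monocytes and macrophages lay barely above the highest other control. NK and T cell markers lay within the range of the other controls. B cell receptor signalling (7.92 against 8.25 to 8.49) and follicular B cells (7.72 against 8.31 to 8.64) lay below the other controls. A narrow signal range of this array, from RNA amount, amplification or hybridisation, predicts the slope and stays open. RNA of other cells alone is argued against by the low ribosomal proteins as deposited and by the background control features. Those averaged 4.20 in this array and 3.17 to 3.64 in the other arrays. RNA of other cells beside a narrow signal range stays open. No biological explanation was tested, since the design names none for a single replicate and RNA of other cells counts as contamination.

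Kindlin-3 KO replicate 4 was apart in 2 cases. It was the lowest Kindlin-3 KO sample for Tagln2, at 8.19 against 8.60 to 8.64 (ratio 0.915), and the highest for the mean of transitional and precursor B cells, at 5.23 against 5.10 to 5.11 (ratio 0.878).

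The 21 lists past camera could reflect the level trend between arrays or a group difference. Such a difference may come from the loss of Kindlin-3 or from Cre in the Cd79a allele, which the design does not separate. For the 17 lists whose call cyclic loess ended, the shift after it had a median ratio of 0.155 to the deposited shift (range -0.066 to 0.565), which is what a level trend predicts, though a true shift that follows expression level would be removed as well. Control replicate 1 alone is argued against, since 18 of the 21 lists kept their call and direction without it. Their shifts fell, however, as from 0.69 to 0.32 for kappa V segments and from 0.62 to 0.18 for B cell receptor signalling, and with an estimated correlation 0 lists passed with or without it. Outside the central 95% of 1000 random lists of equal level, both with and without control replicate 1, lay 7 lists. They were immediate early genes, B cell activation, heavy V segments, kappa V segments, complex I, NK cells and monocytes and macrophages. Random lists matched on level alone make no allowance for members that vary together, so they do not decide against the trend. After cyclic loess immediate early genes, B cell activation and NK cells did not pass camera (adjusted p = 0.52, 0.0561 and 0.117). The number of lists as deposited says nothing about chance, because control replicate 1 is in 1 of the groups in every split and all 35 splits gave 16 to 26 lists, 14 of them at least the real 21 (highest other 26). Chance cannot be excluded for the number after cyclic loess, where 25 of 35 gave 4 or more (highest other 12), or without control replicate 1, where 2 of 35 gave 18 or more (highest other 20). Only 8 of those 35 part all 3 pairs of equal replicate number (real 18, highest other 15), too few for a share under 0.05.

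For the kappa V segments the level trend as the whole cause is argued against by the call after cyclic loess over the 7 arrays other than control replicate 1 (adjusted p = 5.38e-11, list means 6.18 ± 0.12 in 3 controls and 6.41 ± 0.02 in 4 Kindlin-3 KO samples without overlap), although over all 8 arrays after cyclic loess it did not pass with an estimated correlation (adjusted p = 0.785). For the heavy V segments the call held after the same correction (adjusted p = 8.5e-05, shift 0.13), and the list lay outside the random lists of equal level. The list means overlapped after that correction, so the trend is not decided against there. For the kappa shift after cyclic loess 1 of 35 splits, the real one, was as large as 0.468 (highest other 0.399). That is the fewest possible, for a list picked from 34 and a shift that is 0.23 over the 7 arrays, so chance is not excluded. Nor is it for the heavy shift, with 6 of 35 as large as 0.251 (highest other 0.323). Antibody-secreting cells, which the gate on medium CD21 and IgM would largely remove, would bring Jchain, which read 3.98 in control and 3.62 in Kindlin-3 KO as deposited, near background, a difference of -0.36 (SE 0.23). After cyclic loess over the 7 arrays it differed by -0.243 (SE 0.24), an error that reaches the kappa shift of 0.23. Of the other markers on that scale, Mzb1 (0.07, SE 0.13), Sdc1 (-0.01, SE 0.17), Xbp1 (-0.05, SE 0.12), Irf4 (-0.01, SE 0.10), Ighm (-0.23, SE 0.14) and Prdm1 (-0.06, SE 0.06) did not rise by that much. The errors of Mzb1 and Sdc1 reach it, though, Prdm1 reads near background, and Xbp1, Irf4 and Ighm are high enough in follicular B cells to hide a small share, so this explanation is not excluded. A change of kappa V usage, with Kindlin-3 loss or with Cre in the Cd79a allele, stays a hypothesis beside signal shared between related segments, which was not tested. A difference in the purity of the sorted B cells was not tested either. After cyclic loess over all 8 arrays the shift of monocytes and macrophages was -0.23, while that of B cell receptor signalling was 0.08 and did not pass.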

How the results depend on the processing

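The alternatives of cyclic loess over 7 arrays, array weights after cyclic loess, scale normalization, low Xist samples, Xist level as a block and the replicate block over 3 pairs were chosen after the result was seen. Fermt3 was lower in Kindlin-3 KO under all 23 alternatives, by -0.89 to -0.35, and passed the test only with array weights (-0.75). All 24 other named genes kept their direction, and all but Olfr58 passed with array weights, and 9 of low level had no value in the filter on dim genes. Of 846 list values 671 kept direction and side of the threshold, 112 lost the call, 5 gained one and 58 turned. Turns follow the direction of the camera test, which can differ in sign from the shift printed, and but for heat shock, ribosomal proteins, integrins, receptor signalling and follicular B cells they were of lists that did not pass. Except where samples or genes were left out, the cause was not tested.

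The number of genes past the threshold was 0 except for 1047 with array weights, 1 over all rows of the array and 0 to 1 with a sample left out (1 without control replicate 1). Those at an unadjusted p under 0.05 numbered 7335 with array weights, 5882 over all probes, 2028 among genes at or above the median level, where fewer genes were tested, and 1287 to 4726 with a sample left out.

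The lists past camera numbered 8 after quantile normalization, 4 after cyclic loess, 3 after cyclic loess over 7 arrays, 5 with array weights after cyclic loess, 13 among genes at or above the median level, 0 with an estimated correlation and 0 by fry. Heavy V segments (0.504 and 0.5032), kappa V segments (0.6907 and 0.6898), complex I (0.5133 and 0.5138) and monocytes and macrophages (-0.3198 and -0.3185) lost their calls with an estimated correlation and by fry, whose value is the mean log2 fold change. Monocytes and macrophages did so after cyclic loess over 7 arrays too (-0.1832).

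Cd79a turned with array weights (-0.09834), quantile normalization (-0.1296), cyclic loess (-0.2576), cyclic loess over 7 arrays (-0.4724) and array weights after it (-0.3893), and ranged from -0.2014 to 0.6876 with a sample left out, negative only without control replicate 1.

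With trend and robust priors marginal zone B cells (0.1064) and T cells (-0.02527) turned, and with array weights germinal centre B cells (-0.007541). With quantile normalization germinal centre (0.08265) and transitional B cells (-0.01849), T cells (0.04115) and platelets (-0.01816) turned. With median centring marginal zone B cells (0.1064), T cells (-0.02527) and platelets (-0.05108) turned. After cyclic loess germinal centre B cells (0.05715), heat shock (-0.01076), ribosomal proteins (-0.0333), T cells (0.05519), platelets (0.01019) and the sex-linked list (0.05306) turned. Among genes at or above the median level germinal centre (0.01561) and memory B cells (-0.09268) did. Over all probes marginal zone (0.1949) and transitional B cells (0.03344) and T cells (0.01067) did.

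After cyclic loess over 7 arrays integrins (-0.0137), receptor signalling (-0.04083), germinal centre (-0.03989) and follicular B cells (-0.02668), heat shock (-0.03444), T cells (0.0114), dendritic cells (0.02135), platelets (0.00469) and the sex-linked list (-0.06085) turned. With array weights after cyclic loess integrins (-0.008019), receptor signalling (-0.0432), germinal centre (-0.03437) and follicular B cells (0.0155), platelets (0.002052) and the sex-linked list (-0.02503) did. With scale normalization marginal zone (0.1317) and B-1 cells (-0.07732), T cells (-0.03083) and platelets (-0.05544) did, in samples low in Xist marginal zone B cells (0.1727), and by fry germinal centre B cells (0.1075), the cell cycle (0.04436) and interferon response (0.03406). With a sample left out the shift ranged from -0.0141 to 0.1673 for germinal centre, -0.05775 to 0.1948 for marginal zone, -0.1322 to -0.02919 for B-1 and -0.1124 to 0.0634 for transitional B cells, and -0.1514 to 0.11 for T cells.

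With the replicate block 0 genes passed in limma (2268 at an unadjusted p under 0.05), Fermt3 stayed at -0.51 (adjusted p = 0.499) and 21 lists passed. Without control replicate 1, where same-numbered samples deviated together, the replicate block over the 3 pairs left gave 0 genes past the threshold (smallest adjusted p = 0.1495), so that the call of Myadm ended, and 4887 at an unadjusted p under 0.05, with Cd79a (-0.2604), the interferon response (-0.06206), T cells (0.06346) and the sex-linked list (-0.01363) turned. It called 19 lists against 18 without the block, heat shock being the list gained, and changed no other call.

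The background control features averaged 4.20 in control replicate 1 and 3.17 to 3.64 in the other arrays, so differences of genes near those levels are limited by background.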

Other observations

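The gene families were chosen after complex I was seen, while the tests of the hypotheses on them and on the neighbours of Cd79a, and of all splits of the samples, were chosen before their results were seen. Genes of the other respiratory chain complexes and of the proteasome moved with complex I. Of 58 genes of complexes II to V (Cox, Uqcr, Atp5 and Sdh genes) 52 read higher in Kindlin-3 KO as deposited and 47 after cyclic loess, with a shift of 0.172 (camera adjusted over 8 families, p = 2.34e-07; adjusted p = 0.00982 with an estimated correlation). The 9 Uqcr genes of cytochrome bc1 had a shift of 0.26 after cyclic loess, the 20 Atp5 genes of the ATP synthase 0.21 and the 25 Cox genes 0.10 (adjusted p = 0.00158, 1.79e-06 and 0.0379). With an estimated correlation their adjusted p was 0.0635, 0.0413 and 0.135. Proteasome subunits, of which 32 of 38 read higher after cyclic loess, had a shift of 0.22 (adjusted p = 7.02e-10; adjusted p = 0.0066 with an estimated correlation), and the 78 mitochondrial ribosomal proteins one of 0.09 (adjusted p = 0.00247; adjusted p = 0.135 with an estimated correlation). Over the 7 arrays other than control replicate 1 the shift of complexes II to V was 0.15 and that of the proteasome 0.20 (adjusted p = 5.9e-09 and 1.77e-12).

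A candidate explanation is that respiratory chain genes as a class are higher in Kindlin-3 KO follicular B cells, which predicted an upward call for complexes II to V after cyclic loess (0.172, past the test). After cyclic loess only 1 of 35 splits, the real one, reached the shift of complexes II to V (0.172, highest other 0.149). The same held for the proteasome (0.217, highest other 0.163). These counts are the fewest possible and make no allowance for the choice of 8 families after complex I was seen. They therefore do not exclude chance. Complex I, a list picked from 34, led by a small margin only, with 1 of 35 as large as 0.106 (highest other 0.105). The exact permutation test of the complex I list means after cyclic loess, which overlapped, does not exclude chance either (p = 0.0857). The means did not overlap as deposited, without control replicate 1 or after cyclic loess over the 7 other arrays (exact permutation p = 0.0286 each, the smallest possible). Over 7 arrays that p takes all 35 labelings. Only 8 of them part all 3 pairs of equal replicate number, too few for a share under 0.05. These families share a middling to high expression level, and RNA handling that acts on them as a class, or a difference in activation or cell size, was not tested.

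Receptor families of the nose, which B cells are not known to use, followed the level trend. As deposited, 79 of 1224 olfactory receptors and 11 of 492 vomeronasal receptors read higher in Kindlin-3 KO, with shifts of -0.19 and -0.20, and after cyclic loess 641 and 245 did, with shifts of 0.01 and 0.01 (adjusted p = 0.814 and 0.918). The Olfr and Vmn genes among the named genes lay within these families.

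A segment of the donor strain around the Cre-carrying Cd79a allele could carry differences to its neighbours on chromosome 7. Among the 200 tested genes nearest to Cd79a in gene order, 10 had an unadjusted p under 0.05 after cyclic loess, against a median of 18 over 25770 such windows, which placed it at percentile 4.41. Of its 94 genes at or above the median level 8 did, against 12.7% of all such genes. The window around Fermt3 held 25 (percentile 93.1), and 19 without control replicate 1 (percentile 49). The prediction of more such genes beside Cd79a was therefore not met. Of the 24 named genes, however, Vmn1r168 and Blvrb lay in that window and Apoe and Pglyrp1 118 and 163 genes from Cd79a, which was looked at after the result was seen. Only 0.799% of windows of 200 genes on each side held 4 or more of the 24. Of 34 such counts over windows and numbers of genes of smallest p, 5 were reached by under 5% of windows. A count of all genes can miss a segment that alters few of them, so the segment and a loss of Kindlin-3 cannot be told apart for those 4 genes. Tigd3 lay in the Fermt3 window.

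Chance was also set against the counts of genes. For genes past the adjusted threshold the real count was 0, which each of the 35 splits must reach (highest other 1), so that count says nothing about chance. For genes at an unadjusted p under 0.05 as deposited, 1 of 35 splits, the real one, had 3138 or more (highest other 2584). That is the fewest possible, and control replicate 1 is in 1 of the groups in every split, so chance is not excluded. Nor is it after cyclic loess, with 2 of 35 at 2759 or more (highest other 3047), or without control replicate 1, with 2 of 35 at 4720 or more (highest other 4759). The 1 other split that large set Kindlin-3 KO replicate 3 with control replicates 1 to 3 after cyclic loess, and with control replicates 2 to 4 without control replicate 1. That last split leaves the pair numbered 3 in 1 group. Of the 35 splits without control replicate 1, 8 part all 3 pairs as the real one does, with a real count of 4720 and a highest other of 1486, and 8 splits are too few for a share under 0.05.

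Xist, the RNA of the inactive X chromosome, read 9.46 and 9.54 in replicate 4 of both groups and 3.09 to 3.82 in the other 6 samples, and the Y-linked Eif2s3y read 4.13 and 4.00 in replicate 4 and 5.16 to 5.93 in the others. The second principal component (8.89% of the variance) parted replicate 4 of both groups, at 28.2 and 24.9, from the other 6 samples, at -12.5 to 1.96, while the first (78.6%) parted control replicate 1. Il9r, chosen after its values were seen, read 5.38 ± 0.35 in control and 6.78 ± 0.54 in Kindlin-3 KO (SD, n = 4 each), a log2 fold change of 1.40 (SE 0.28, limma adjusted p = 0.409) and 1.17 after cyclic loess.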
